A study of Mus musculus with 12 samples.

How the data were processed

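The series measured dissociated lung tissue of benzo[a]pyrene-treated mice in 12 GEO samples, 4 assays in each of 3 groups. The assays were single-cell RNA sequencing, sample-tag (hashtag) sequencing, T cell receptor sequencing and B cell receptor sequencing. Per the labels' protocols, libraries were made on the BD Rhapsody system and sequenced on an Illumina NovaSeq instrument. Groups A, B and C had 0, 4 and 8 weeks of cessation after 6 weeks of exposure, with 32 mice planned per group per the series' design text. Untreated mice were not analysed here. All labels give batch 1. The treatment label reads Smoking, while the design text describes gavage of benzo[a]pyrene.

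The authors deposited a table of counts of cells for 15 cell types in 9 named samples. How the cell types were assigned and which cells were filtered out is not given in the sources used here. Seurat 4.3.0 and the mouse builds mm10 and GRCm38 are named per the submitters' processing notes. The aligner and the caller of receptor sequences are not given in the sources used here. For receptors, the authors deposited counts of cells per clonotype, written as the CDR3 amino acid sequences of both chains. They also deposited diversity indices, which are scores of differing scales, and overlap indices and size classes, which are fractions from 0 to 1. A column of distinct clonotypes as a percent of receptor-bearing cells was deposited by the authors as well. The deposited overlap equalled the Morisita-Horn index computed here. The deposited CDR3 lengths counted the letters that mark a missing chain, so lengths were computed from the sequences instead. The authors deposited the expression matrix as raw counts of unique molecules (UMIs) for 31940 gene symbols and 130467 cells, of which 31770 genes had a count. Deposited tables of numbered clusters, ranked clones and rarefaction were not used here, and no column of samples was left unused elsewhere.

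Samples were assigned to groups by the letter of their names. Shares were computed per sample over all its cells, and groups were compared as mean and SD of 3 samples. Differences of means were tested with a two-sided exact permutation test over the 20 splits of 3 against 3, whose smallest p is 0.10, and called by whether the samples of the groups overlapped. Tests over all 3 groups were added after the data were seen and permuted the labels over 280 partitions (1680 labelled splits), with a smallest p of 0.0036. Benjamini-Hochberg adjustment ran over 15 cell types and over 3 compartments. Every receptor sample was thinned to the smallest sample, 2456 cells for B and 1007 cells for T cell receptors, as the mean of 1000 seeded draws. Overlap within against between groups was tested one-sided over the 280 partitions.

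Cell names in the matrix end in 1, 2 or 3. The numbers of cells with these endings, 43643, 46502 and 40322, equal the totals of groups A, B and C in the cell type table, but no label ties an ending to a group, so none was assigned. The endings are called libraries 1, 2 and 3. Expression by group and gene list shifts by group, both part of the plan, were therefore not computed by group. The matrix is described as 1 pooled sample, and values per library stand side by side without tests. Libraries held 122049554, 107705194 and 96438560 UMIs, with medians of 2030, 1710 and 1586 UMIs and 1156, 1017 and 984 genes per cell and median mitochondrial shares of 4.21%, 4.36% and 4.45%. The cells held at least 602 UMIs and between 401 and 4997 genes, and at most 20.0% mitochondrial counts, and no further filter was applied.

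Cells were clustered on 2000 variable genes, 40 principal components and a graph of 20 neighbours with at least 4 shared, by the Leiden method at resolution 1, which gave 61 clusters of at least 50 cells. Clusters were named from 36 fixed marker lists, using markers detected in at least 20% of cells and at least 3 markers per name, and gave 23 named classes. A cluster was set apart as mixed when the markers of another lineage had a mean log2 fold of at least 0.5 and of at least 25% of that of the best list, a rule set after the clusters were seen. Mixed clusters held 6.43%, 7.14% and 4.87% of libraries 1, 2 and 3, unnamed clusters 2.93%, 1.61% and 2.09%, and smaller clusters 0.176% of all cells. No doublet caller was run. Cells with at least 3 UMIs of markers from 2 of 7 lineages were 22.2%, 15.5% and 15.8% of the libraries. They were kept, and leaving them out was an alternative.

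Expression in a class was the sum of its counts, scaled to the class's total count (CPM), with 95% exact Poisson intervals, and ratios of libraries with exact conditional binomial intervals. Both cover counting error only. Genes were named by a fixed rule, which was applied to libraries 2 and 3 against library 1. It took the 5 highest and 5 lowest log2 ratios among genes with at least 100 counts and 50 CPM in classes of at least 200 cells per library, plus members of 31 fixed gene lists. The marker lists, the gene lists, the naming rule and the planned tests and alternatives were fixed before the data were examined. Only some of the genes the rule names are described, leaving out genes that lead the clusters concerned, except Cyp1a1, which is among the 10 leading genes of 1 smaller endothelial-like cluster. A list's median ratio used members with at least 50 counts and was ranked among 10000 random lists matched on expression in 20 bins.

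Steps were checked on simulated data with known answers. For B cell-like cells of library 2 with library 1, 200 of 11749 genes were changed 2-fold, intervals covered the true ratio for 95.4% of genes, and the median log2 of doubled and halved genes was 1.00 and -1.00. For endothelial-like cells, with 9190 genes, these were 95.9%, 0.99 and -1.02. The simulated counts were Poisson draws, the model that the intervals assume, without variation between cells or samples. Coverage near 95% thus checks the calculation only, not whether that model holds for these data. Alternatives were other denominators, leaving out each sample, other clone definitions and depths, other scalings, thinning to 1000 UMIs, and leaving out marker doublets. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9 were used.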

Results

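Female Kunming mice, an outbred stock, were given benzo[a]pyrene, a polycyclic aromatic hydrocarbon found in tobacco smoke, by gavage for 6 weeks from the age of 5 weeks. Lungs of group A were taken with 0 weeks of cessation, lungs of group B after 4 weeks without the compound, and lungs of group C after 8 weeks. Dissociated lung tissue with visible nodules was profiled by single-cell RNA sequencing, sample-tag sequencing and sequencing of B and T cell receptors. Each of the 4 assays had 1 library per group, 12 GEO samples in all, so library and group cannot be told apart, and age at sampling differed along with cessation time. The deposited tables named 9 samples, 3 in each group, which are called A1 to A3, B1 to B3 and C1 to C3 here. The labels do not say that these were separate animals, so the p-values below measure only the spread between these samples, which may be technical. The cell type table held 130467 cells, with 11657 to 16279 per sample and 43643, 46502 and 40322 cells in groups A, B and C. B cell receptors were recorded for 2456 to 6393 cells per sample and T cell receptors for 1007 to 3104.

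The first comparison asked how the cell composition of the lung differed with time since exposure. Lymphocytes, taken as the sum of B, plasma, T and NK cells, were 33.2% ± 10.3 (SD, n = 3) of the cells in group A, 75.1% ± 21.8 in group B and 57.3% ± 16.4 in group C. Group B held 2.26 times and group C 1.73 times the share of group A, with all 6 samples of groups B and C above the 3 of group A. NK cells, the cytotoxic innate lymphocytes, made up 1.37% ± 0.271 of cells in group A, 3.95% ± 1.65 in group B and 2.61% ± 0.780 in group C, and again no sample of group B or C overlapped with group A. B cells were 12.6% ± 5.68 of cells in group A and 34.7% ± 20.5 in group B, 2.75 times as many with no overlap, and 26.8% ± 14.3 in group C, where the samples did overlap with group A. T cells were 18.8% ± 5.97, 35.8% ± 14.7 and 27.5% ± 4.92, with overlap in both comparisons against group A. Plasma cells were 0.421% ± 0.211, 0.638% ± 0.201 and 0.443% ± 0.0460 of cells and separated groups B and C from group A only without A2, at 2.13 and 1.48 times its share. Within the lymphocytes the makeup overlapped between groups for every one of the 4 types. NK cells were 4.29%, 5.68% and 4.96% of lymphocytes, 1.32 times group A in group B and 1.16 times in group C, B cells 37.4%, 45.3% and 44.8%, and T cells 57.1%, 48.1% and 49.4%.

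In two-sided exact permutation tests the smallest p that 3 against 3 samples allow is 0.10, so no pairwise comparison could reach 0.05, and groups that did not overlap are named as such, which chance alone gives in 10% of such comparisons. Lymphocyte and NK cell shares reached p = 0.10 for B against A and for C against A in the exact permutation test, B cells p = 0.10 and 0.20, and T cells p = 0.20 in both. An exact permutation test over the 3 groups, added after the data were seen, gave p = 0.046 for lymphocytes and 0.046 for NK cells. With Benjamini-Hochberg adjustment these became 0.070 over 3 compartments, higher in 6 of 6 samples, and 0.188 over 15 cell types, so neither passed 0.05. Within lymphocytes alone, a comparison also added after the data were seen, the NK cell share gave an exact permutation p of 0.40 for B and 1 for C against A, and the B cell share 0.60 and 0.50. Lymphocytes were 94.4% of cells in B1, 79.4% in B2 and 51.5% in B3, and leaving out B1 lowered the B cell ratio of B to A from 2.75 to 1.81. Leaving out B1 and B2 lowered the T cell ratio from 1.91 to 1.22.

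**Figure D1:**
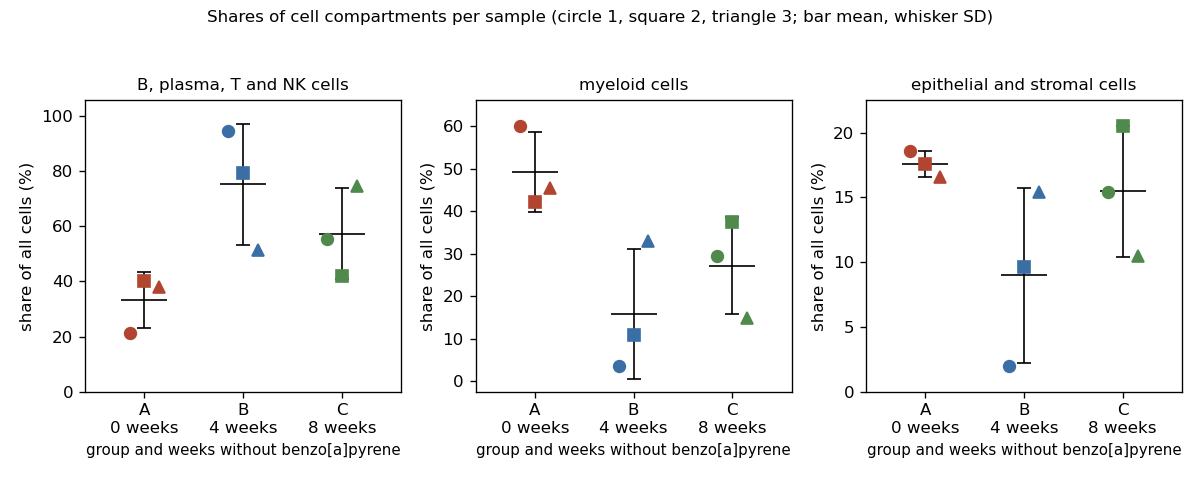
Share of all cells, in percent, held by lymphocytes, myeloid cells, and epithelial and stromal cells in the 9 samples, by group and weeks without benzo[a]pyrene, with a symbol for each sample, a bar for the group mean and a whisker for the SD. Lymphocytes reached 94.4% in B1, while group A lay between 21.4% and 40.3%.

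Myeloid cells held lower shares of all cells in groups B and C than in group A. Together they were 49.2% ± 9.50 of cells in group A, 15.9% ± 15.3 in group B and 27.2% ± 11.4 in group C, 0.323 and 0.553 times group A without overlap. Monocytes were 13.5% ± 6.03 of cells in group A, 2.81% ± 4.10 in group B and 4.38% ± 2.66 in group C, 0.209 and 0.325 times group A and lower in 6 of 6 samples. Neutrophils were 16.8% ± 7.33, 7.86% ± 5.56 and 6.96% ± 2.41, and only group C stood apart from group A, at 0.414 times its share. Macrophages that the authors called M2 made up 11.8% ± 2.67 of cells in group A, 2.81% ± 4.01 in group B and 9.40% ± 4.59 in group C. M1 macrophages were 3.67% ± 0.593, 1.21% ± 1.04 and 2.99% ± 1.06, and dendritic cells, which present antigen to T cells, 3.16% ± 1.16, 0.938% ± 0.883 and 3.23% ± 1.84. These last 3 types were lower in every sample of group B than in any of group A, at 0.239, 0.329 and 0.297 times its share, and overlapped with group A in group C. Among cells other than lymphocytes monocytes were at 0.394 times group A in group B and 0.487 times in group C, and neutrophils in group C at 0.672 times, without overlap. For monocytes in group B this rested on B1 and B2, at 4.49% and 3.15%, since B3 at 15.6% (14.8 to 16.4, exact binomial 95% interval) and A3 at 15.8% (15.0 to 16.6) differed by less than counting error. The ratio was 0.195 without B3 and 0.792 without B1 and B2. In group B neutrophils were then 36.0% against 24.5% in group A, 1.47 times, which is the opposite direction, dendritic cells 1.02 times, M1 macrophages 0.749 times and M2 macrophages 0.437 times, all with overlap. Leaving out 1 sample separated neutrophils (1.71 without A1, 1.64 without B3), M1 macrophages (0.509 without B2) and M2 macrophages (0.367 without A1, 0.236 without B3), while dendritic cells were at 0.576 times without B1 with overlap. Mast cells were 0.287% ± 0.137, 0.252% ± 0.234 and 0.267% ± 0.0342 of all cells, with overlap unless B3 was left out, when group B was at 0.420 times group A, and 0.447%, 1.04% and 0.679% of cells other than lymphocytes, where group B lay above group A without overlap.

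Monocytes and the myeloid sum gave an exact permutation p of 0.10 against group A in both comparisons, the smallest possible. Neutrophils gave exact permutation p = 0.20 for B and 0.10 for C, and M2 macrophages 0.10 and 0.70. Over the 3 groups the exact permutation p was 0.039 for monocytes, 0.188 after adjustment over 15 cell types, and 0.043 for the myeloid sum, 0.070 after adjustment over 3 compartments. The values of group B rested on single samples. Without B3 the B to A ratio was 0.033 for monocytes, 0.148 for the myeloid sum, 0.043 for M2 macrophages, 0.204 for M1 macrophages and 0.136 for dendritic cells. Without B1 and B2 it was 0.559 for monocytes, 0.672 for the myeloid sum, 0.630 for M2 macrophages, 0.579 for M1 macrophages, 0.618 for dendritic cells and 0.803 for neutrophils. Without C2 the C to A ratio of M1 macrophages was 0.665, without overlap.

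Among epithelial cells, alveolar type 1 cells, the thin cells of the gas exchange surface, were 0.617% ± 0.191 of cells in group A, 0.123% ± 0.163 in group B and 0.642% ± 0.396 in group C. Group B stood below both other groups without overlap, at 0.199 times group A, and group C held 5.23 times the share of group B. Most of these cells of group B lay in B3, 50 against 2 in B1 and 7 in B2, so the ratio of C to B depends on B3. Club cells, secretory cells of the airway, were 0.904% ± 0.164, 0.386% ± 0.313 and 0.733% ± 0.191, and fibroblasts 5.91% ± 0.689, 3.64% ± 1.62 and 6.49% ± 1.79. Both were lower in every sample of group B than in any of group A as shares of all cells, but not among cells other than lymphocytes. There fibroblasts were 9.04%, 21.0% and 16.4%, 2.33 times group A in group B with overlap and 1.82 times in group C without, and club cells were 1.39%, 1.71% and 2.03%, with overlap. The fibroblast ratio of B to A was 2.57 without A3 and 2.94 without B3, both without overlap, and 1.10 without B1 and B2, and the club cell ratio was 0.665 without B2. Alveolar type 1 cells were 0.400 times group A in group B on that basis. That ratio rested on 2 cells in B1 and 7 in B2, while B3 at 0.639% (0.475 to 0.842) and A3 at 0.689% (0.526 to 0.885) differed by less than counting error, and it was 0.252 without B3 and 0.698 without B1 and B2. Alveolar type 2 cells, which make surfactant, were 2.27% ± 0.558, 1.10% ± 1.28 and 2.35% ± 0.633 of cells and endothelial cells 7.88% ± 1.13, 3.76% ± 4.73 and 5.25% ± 3.35, with overlap between groups. Among cells other than lymphocytes type 2 cells were 3.38%, 4.69% and 5.77%. There they were 1.39 times group A in group B with overlap, and 1.71 times in group C without overlap. As shares of all cells the samples of group B lay far apart, with endothelial cells at 0.101% in B1, 2.08% in B2 and 9.099% in B3 and type 2 cells at 0.0202%, 2.504% and 0.762%. The sum of these epithelial and stromal types was 17.6% ± 0.986 in group A, 9.0% ± 6.75 in group B and 15.5% ± 5.02 in group C. For B against A the exact permutation p was 0.10 for alveolar type 1 cells, club cells and fibroblasts, 0.30 for alveolar type 2 cells and 0.40 for endothelial cells, and no cell type had an adjusted p below 0.188 over the 15. Without B3 the alveolar type 1 ratio of B to A was 0.047, without B1 and B2 it was 0.502, and without B2 the club cell ratio was 0.266. The endothelial ratio of B to A moved from 0.477 to 0.138 without B3, where the groups no longer overlapped, and to 1.15 without B1 and B2. The type 2 ratio moved from 0.482 to 0.172 without B2, again without overlap. For C to A, the alveolar type 1 ratio was 0.669 without C2 and the club cell ratio 0.741 without A1, both without overlap. Shares add up to 100% within a sample, so a larger lymphocyte share lowers all others, and the comparison among cells other than lymphocytes was added after the data were seen.

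The B cell receptor libraries addressed clonal diversity and expansion, with a clone defined by the CDR3 amino acid sequences of the chains that were found, so that cells with a light chain alone count as 1 clone when that chain matches. By this definition B cell clones of group A were the least diverse. After thinning every sample to 2456 cells, the inverse Simpson index, the number of equally large clones that would give the same evenness, was 104 ± 51.0 (SD, n = 3) in group A, 950 ± 187 in group B and 707 ± 82.2 in group C. The Shannon index was 6.48 ± 0.197, 7.28 ± 0.119 and 7.10 ± 0.0636. The largest entry held 8.81% ± 2.33 of receptor-bearing cells in group A, 0.714% ± 0.242 in group B and 1.08% ± 0.429 in group C, and in all 9 samples it was a light chain without a heavy chain, which unrelated B cells can share. The most frequent heavy chain held 6.28% ± 0.655 of heavy chain entries in group A, 0.319% ± 0.131 in group B and 0.706% ± 0.282 in group C, and the largest clone with both chains named 2.49% ± 0.231, 0.210% ± 0.123 and 0.225% ± 0.120 of such cells. Clones of 2 or more cells held 54.1% ± 1.85, 39.3% ± 6.00 and 46.7% ± 3.36 of the cells. These shares rested mainly on entries with 1 chain. Among cells with both chains named, such clones held 6.50% to 9.18% in samples of group A. They held 0% to 0.480% in group B and 0.212% to 0.575% in group C.

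For each of these measures no sample of group B or C overlapped with group A, with an exact permutation p of 0.10 for either comparison and of 0.0036 over the 3 groups for both thinned indices, the smallest these partitions allow. In the authors' deposited table the inverse Simpson index averaged 110 in group A, 498 in group B and 448 in group C. The ratio of the thinned inverse Simpson index was 9.17 for B to A and 6.83 for C to A. It was 4.71 and 4.37 with the heavy chain alone, and 3.26 and 2.55 with the most abundant clone left out. The Shannon differences of 0.797 and 0.613 became 0.373 and 0.340 with the heavy chain alone and 0.443 and 0.278 without that clone. The difference of -14.8 percentage points in expanded cells between B and A was -7.36 among cells with both chains.

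**Figure D2:**
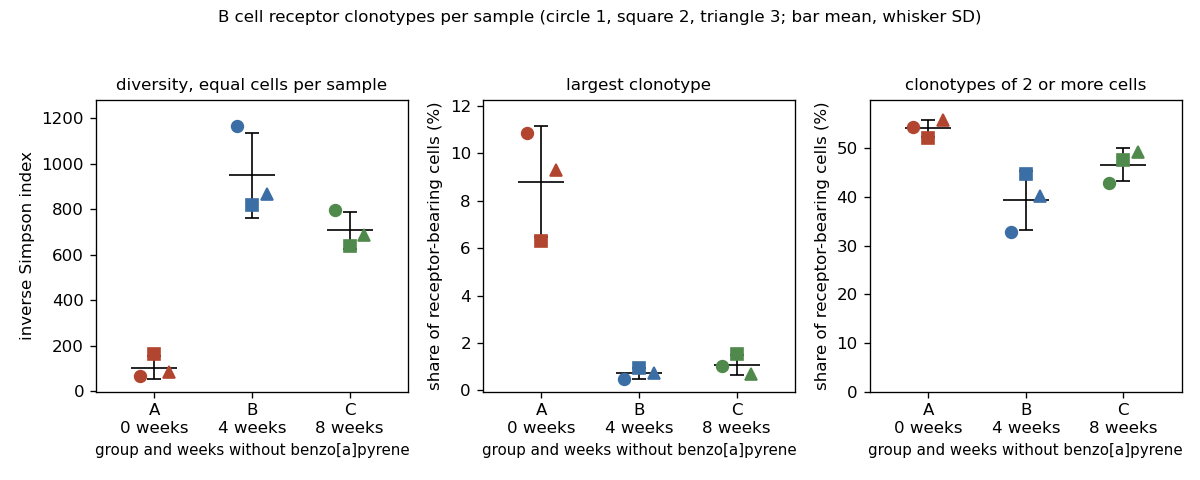
B cell receptor clones in the 9 samples, by group and weeks without benzo[a]pyrene: inverse Simpson index after thinning to 2456 cells, and percent of receptor-bearing cells in the largest clone, a light chain alone in all 9 samples, and in clones of 2 or more cells, with a symbol for each sample, a bar for the group mean and a whisker for the SD. The index averaged 104 in group A, 950 in group B and 707 in group C.

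Receptors typical of innate-like B cells were counted as well. A short set of light chain CDR3 sequences typical of phosphatidylcholine-binding B-1a cells, innate-like B cells with public receptors, was carried by 16.3% ± 3.21 of receptor-bearing cells in group A, 1607 cells, against 1.08% ± 0.480 in group B and 1.46% ± 0.528 in group C. Heavy chain CDR3 sequences of the same kind made up 7.83% ± 1.37 of heavy chain entries in group A, 0.461% ± 0.346 in group B and 0.881% ± 0.337 in group C. Both sets were chosen after their values were seen, so no test is given. The most frequent heavy chain and the largest entry of group A belong to them.

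Chain recovery differed with the group as well. Per 100 cells that the authors annotated as B or plasma cells, 191 ± 43.4 cells carried a B cell receptor entry in group A, 93.8 ± 18.1 in group B and 117 ± 17.9 in group C, so in group A more cells held an immunoglobulin sequence than were annotated as making one. Whether such entries moved the diversity, the clone sizes or the shares of innate-like receptors in group A was not tested. Entries with a light chain alone were 59.4% ± 2.22, 44.8% ± 5.51 and 54.8% ± 1.39, entries with a heavy chain alone 7.18% ± 1.67, 35.7% ± 4.14 and 15.9% ± 2.09, and entries with both chains 33.4% ± 3.88, 19.5% ± 1.52 and 29.3% ± 1.13. All 3 pairs of groups were apart on each of these chain classes, with an exact permutation p of 0.10.

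Samples of a group overlapped more in their B cell entries than samples of different groups, while clones with both chains named were shared mainly within group A. The deposited overlap index, which equals the Morisita-Horn index computed from the clone counts and runs from 0 to 1, was 0.861 to 0.964 between samples of group A, 0.639 to 0.747 within group B and 0.660 to 0.733 within group C. Between groups it averaged 0.222 for A with B, 0.215 for A with C and 0.542 for B with C. The mean within groups, 0.762, exceeded the mean between groups, 0.326, by 0.436. T cell clones overlapped much less, by 0.0956 within and 0.0340 between groups, a difference of 0.0616. No other of the 280 partitions of the 9 samples into 3 groups of 3 gave a difference as large for B or T cells, a one-sided exact permutation p of 0.0036, the smallest possible. The B cell difference was 0.340 with the heavy chain alone and 0.148 with both chains named, and that of T cells 0.131 with the beta or delta chain alone and 0.0199 with both chains, with exact permutation p of 0.0036, 0.0071, 0.0036 and 0.036. The differences with both chains came from group A. Its B cell pairs had an overlap of 0.404 to 0.513 with 11 to 18 shared clones, while pairs within group B had at most 0.00407 with 0 to 2 shared clones and pairs within group C at most 0.00360 with 0 to 4, below the highest pair of A with B, 0.0349. The largest B cell clone with both chains was the same in A1, A2 and A3, at 2.55%, 2.69% and 2.24% of such cells. Its chains are of the public, phosphatidylcholine-binding kind described above. How much of the overlap within group A it made up was not computed. For T cells with both chains named, pairs within group A shared 6 to 15 clones and pairs within groups B and C shared 0. Such cells numbered 856 to 1387 per sample in group A, but 54 to 76 in group B and 110 to 125 in group C. With so few cells a shared clone could hardly be seen, so for T cells this does not tell the groups apart.

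**Figure D3:**
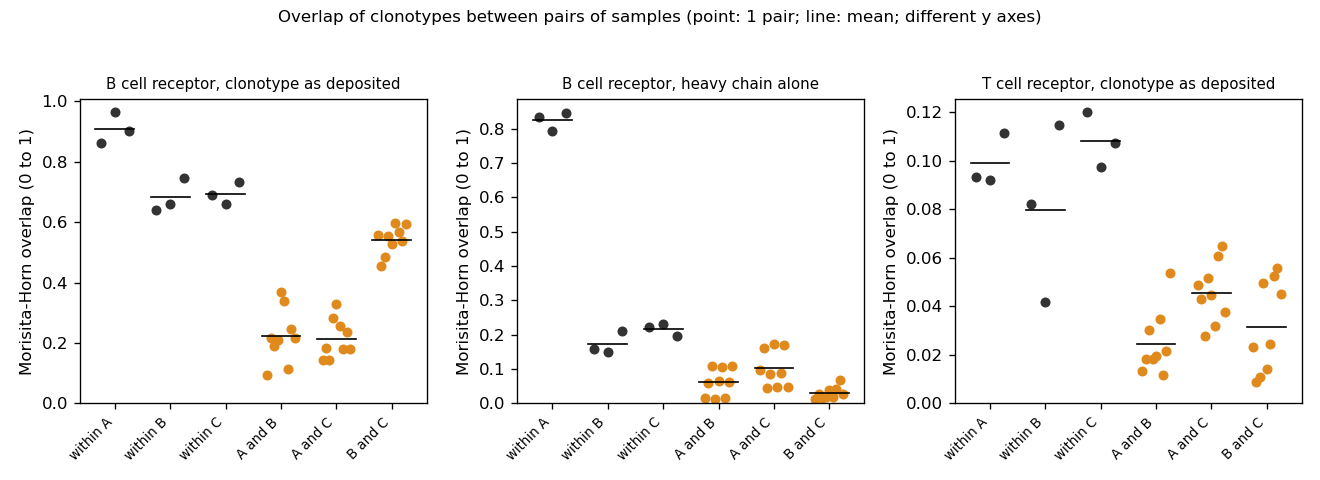
Morisita-Horn overlap of clones, from 0 to 1, for pairs of samples within and between groups, for B cell receptor clones as deposited, B cell receptor heavy chains alone and T cell receptor clones as deposited, on different y axes, with a point for each pair and a line for the mean. B cell receptor pairs within group A lie between 0.861 and 0.964, and pairs of group A with group B average 0.222.

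T cell clones as deposited did not separate the groups at equal depth, where nearly every cell had its own clone. By this definition cells of 1 clone count apart when different chains were found, and chain recovery differed between groups. In A2 the most frequent beta or delta chain was found in 59 cells, while the largest clone as deposited, that chain alone, held 26. Thinned to 1007 cells, samples held on average 963 clones in group A, 985 in group B and 957 in group C, so both indices lay close to their maximum and had little room to differ. The inverse Simpson index was 865 ± 79.4 (SD, n = 3) in group A, 924 ± 44.7 in group B and 847 ± 119 in group C, and the Shannon index 6.84 ± 0.0458, 6.88 ± 0.0150 and 6.83 ± 0.0647. The samples overlapped in every pair of groups, with exact permutation p from 0.30 to 0.80. With the beta or delta chain alone, group B was more diverse than group A without overlap, by 1.32 times in the inverse Simpson index and 0.126 in the Shannon index, with an exact permutation p of 0.10. Clones of 2 or more cells held 9.82% ± 5.54 of cells in group A, 4.11% ± 0.943 in group B and 9.54% ± 4.50 in group C. Group B lay below both others without overlap at p = 0.10 in the exact permutation test, but at equal depth the shares were 6.73%, 3.55% and 7.95%, with an exact permutation p of 0.20 for B against A. The difference of -5.71 percentage points between B and A was -2.52 without A2.

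Fewer cells with a T cell receptor were recorded per annotated T cell after cessation. Per 100 annotated T cells, 97.4 ± 8.65 cells had a receptor in group A, 24.7 ± 2.46 in group B and 39.1 ± 3.19 in group C. A1 had 107, more than its annotated T cells, so there at least some receptors lay in cells not annotated as T cells. Both chains were found in 45.9% ± 2.17, 4.71% ± 0.595 and 8.21% ± 0.846 of receptor-bearing cells. No groups overlapped on either measure, with an exact permutation p of 0.10 for each pair and 0.0036 over the 3 groups. Invariant receptors were rare. The V-delta 1 delta chain of innate-like gamma delta T cells was found in 82 cells of group A, 3 of group B and 7 of group C, or 1.03% ± 0.234, 0.0993% ± 0.172 and 0.173% ± 0.188 of receptor-bearing cells. The V-gamma 6 chain, which pairs with it in interleukin 17 producing gamma delta cells, was found in 68, 6 and 35 cells, 0.843% ± 0.141, 0.199% ± 0.344 and 0.839% ± 0.442 of receptor-bearing cells. In group B the cells with V-delta 1 and those with V-gamma 6 all lay in B3. The alpha chain of invariant NKT cells, which respond to lipids, was found in 54, 12 and 19 cells, 0.667% ± 0.127, 0.299% ± 0.117 and 0.451% ± 0.363. Because chain recovery differed, shares of cells with the same kind of chain were taken as well, and these were 1.37%, 0.167% and 0.278% for V-delta 1, 1.19%, 0.432% and 1.82% for V-gamma 6, and 0.942%, 0.658% and 0.985% for the NKT chain. No test is given for these chains.

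**Figure D4:**
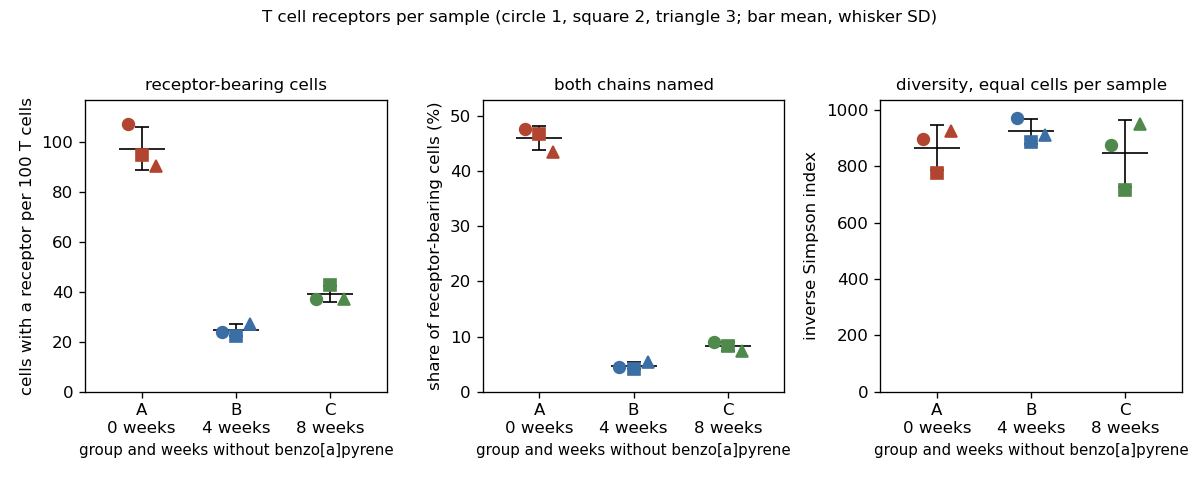
T cell receptors in the 9 samples, by group and weeks without benzo[a]pyrene: receptor-bearing cells per 100 annotated T cells, percent of receptor-bearing cells with both chains, and inverse Simpson index after thinning to 1007 cells, with a symbol for each sample, a bar for the group mean and a whisker for the SD. Receptor-bearing cells per 100 T cells averaged 97.4, 24.7 and 39.1 in groups A, B and C.

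CDR3 loops of T cells were slightly longer on average in group A, while median lengths overlapped. The median was 14 amino acids for beta or delta chains in all 9 samples. For alpha or gamma chains it was 13 or 14 in samples of every group. The mean length of alpha or gamma chains was 14.005 ± 0.108 amino acids (SD, n = 3) in group A, 13.65 ± 0.148 in group B and 13.75 ± 0.0816 in group C, and that of beta or delta chains 14.27 ± 0.0254, 13.99 ± 0.141 and 14 ± 0.102. For both kinds of chain the sample means of groups B and C lay below group A without overlap, with an exact permutation p of 0.10. The test over 3 groups gave an exact permutation p of 0.021 and 0.036. No test of length was planned. Chain recovery differed between these groups, and whether it moved the lengths was not tested. Immunoglobulin heavy chains averaged 13.7, 13.7 and 13.8 amino acids and light chains 10.9 in each group, with overlap between groups.

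The gene expression matrix held 130467 cells whose group could not be taken from any label, so it was read as 1 pooled sample without comparison between groups. Cell classes named from fixed markers are called X-like, and intervals are 95% exact Poisson intervals that cover counting error only. The question was where the machinery for handling benzo[a]pyrene was expressed. Cyp1a1, the cytochrome P450 that oxidises benzo[a]pyrene and a target of the aryl hydrocarbon receptor, was highest in endothelial-like cells, at 907 CPM (counts scaled to the total of the class; 890 to 924). Within them it reached 1164 CPM (1129 to 1200) in aerocyte-like cells, the capillary cells of gas exchange, and 728 (709 to 749) in general capillary-like cells. It was also among the 10 leading genes of a smaller endothelial-like cluster of 486 cells and of a mixed cluster of 321 cells that was left out of the class. The lymphatic endothelial-like class of 537 cells had 186 CPM (164 to 210), but 60.3%, 53.1% and 47.3% of its cells in the 3 libraries carried markers of 2 lineages. At clustering resolution 2 only 173 of them kept the name, and these had 18.96 CPM (9.47 to 33.9), while 348 fell into a cluster with capillary and B cell markers and had 282 (246 to 321). Alveolar type 1-like cells had 129 CPM (113 to 147), with endothelial markers at a mean of 1.21 log2 units above all other cells. Without cells that carried markers of 2 lineages, 27.5%, 23.2% and 15.7% of the class, they had 86.6 CPM (70.9 to 105) and the endothelial markers were still at 0.44. Alveolar type 2-like cells had 1.15 CPM (0.525 to 2.18), with endothelial markers at -2.55. These values by resolution and without doublets were added after the data were seen. B cell-like cells, which serve as background, had 3.12 (2.63 to 3.68). At least 1 Cyp1a1 molecule was seen in 58.4% of endothelial-like and 0.442% of B cell-like cells, whose median depths were 1865 and 1437 molecules. Ahr, the receptor gene itself, was at 129 CPM (123 to 136) in endothelial-like cells and 10.9 (9.996 to 11.9) in B cell-like cells.

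Other target genes were highest in other classes. Cyp1b1 was at 66.4 CPM (62.7 to 70.3) in fibroblast-like cells against 0.742 in B cell-like cells. Lrat, an enzyme of retinol storage, was at 212 (205 to 219) in fibroblast-like cells and 0.633 in B cell-like cells, and Aldh3a1, an aldehyde dehydrogenase, at 173 (161 to 186) in airway epithelial-like cells and 0.633 in B cell-like cells. Of the 12 aryl hydrocarbon receptor genes in the list, 3 were at least 2-fold above all other cells in endothelial-like cells, and the median of the list was 0.03 log2 units. NRF2 and glutathione genes, which detoxify reactive metabolites, had their highest list median in airway epithelial-like cells, at 1.28 log2 units. There 8 of 14 were at least 2-fold above other cells. Among them Gstm1, a glutathione transferase, was at 2176 CPM (2132 to 2221) in airway epithelial-like and 22.5 in B cell-like cells, Gclm at 209 and 58.8, and Gpx2 at 135 and 0.218. Hmox1, which degrades haem, was highest in interstitial macrophage-like cells, at 333 CPM against 8.18 in B cell-like cells.

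Of 16 p53 and DNA damage genes, 5 were at least 2-fold above other cells in alveolar macrophage-like cells, the class with the highest median, 0.36 log2 units. Cdkn1a, a cell cycle inhibitor induced by p53, was at 716 CPM (689 to 744) in aerocyte-like, 532 (520 to 544) in classical monocyte-like and 55.5 in B cell-like cells. Inflammatory cytokine and chemokine genes had their highest list median in interstitial macrophage-like cells, at 1.68 log2 units, with 9 of 16 at least 2-fold above other cells. There Cxcl1 was at 1834 CPM (1812 to 1856) and Ccl2 at 1309 (1290 to 1328), against 30.5 and 7.44 in B cell-like cells. Tnf was highest in alveolar macrophage-like cells, at 1159 CPM (1149 to 1168) against 76.9. Complement C3 was at 6235 (6062 to 6412) in mesothelial-like and 14.6 in B cell-like cells. Cells with markers of 2 lineages, 22.2%, 15.5% and 15.8% of the 3 libraries in the matrix, were kept, so part of a level can come from a second cell in the same well.

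**Figure D5:**
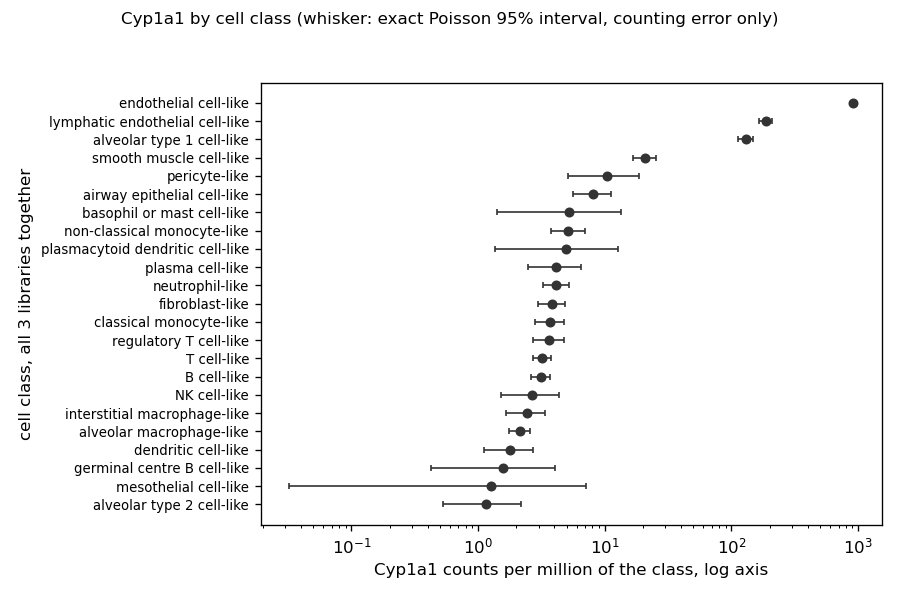
Cyp1a1 CPM of each cell class of the pooled matrix, on a log axis, with a point for the class and a whisker for its 95% exact Poisson interval, which covers counting error only. Endothelial-like cells stand at 907 and B cell-like cells at 3.12, and the lymphatic endothelial-like point at 186 includes 348 cells that lost that name at resolution 2.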

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

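Alternatives were planned together with the tests, except the values without B1 and B2, the shares among lymphocytes and among other cells, the Cyp1a1 levels by resolution and without doublets, the tests over 3 groups, the permutation test of overlap and the expanded share at equal depth, which were chosen only after the results were seen. The tests of CDR3 length were not planned either. With 3 against 3 samples no exact permutation p can pass 0.05, so a comparison was called by whether its groups overlapped. Of 441 alternative values for 54 share results, 389 kept their call, 5 lost separation, 39 gained it, 4 moved, 4 that were separate turned round, and 50 in all changed direction. Among lymphocytes the B to A ratio was 1.21 for B cells and 1.32 for NK cells and the C to A ratio of NK cells 1.16, all with overlap. Among other cells the B to A ratio was 2.33 for fibroblasts, 1.23 for club cells and 1.02 for dendritic cells, and the C to B ratio of fibroblasts 0.781, with overlap in each and the direction turned. This follows from leaving the lymphocytes out of the total. Leaving out samples there as well gave 220 values, of which 197 kept their call, 18 gained separation and 5 moved, with 28 changes of direction. Of 194 for 22 receptor results, 172 kept their call, 7 lost separation, 10 gained it, 5 moved and 17 changed direction. Of 84 for 12 CDR3 length results, 75 kept their call and 9 gained separation, with 3 changes of direction. Under the planned omission of each sample, the lymphocyte ratio ran from 1.92 to 2.62 for B to A and from 1.46 to 1.96 for C to A, the myeloid ratio from 0.148 to 0.448 and from 0.450 to 0.679, and the B cell receptor inverse Simpson ratio from 7.78 to 12.8 and from 5.79 to 9.50, without overlap in any of these. The overlap difference ran from 0.346 to 0.482 for B and from 0.0578 to 0.0698 for T cell receptors.

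Some results gained separation when 1 sample was left out. The B cell ratio of C to A, with overlap at 2.12, ran from 1.48 to 2.79 and separated without A2 (2.79) or C2 (2.54). The T cell ratio ran from 1.48 to 2.26 for B to A, separating without A3 (2.25) or B3 (2.26), and from 1.26 to 1.72 for C to A, separating without A3 (1.72) or C2 (1.61). The neutrophil ratio of B to A ran from 0.300 to 0.631 and separated without A2 (0.392) or B3 (0.300). The T cell receptor Shannon difference of B minus A ran from 0.0114 to 0.0549 and separated without A3 (0.0549). Fewer samples overlap less often by construction. T cell receptor diversity also depended on depth and clone definition. At the depth as deposited, the inverse Simpson ratio was 0.638 for B to A and 0.623 for C to A and the Shannon difference of C minus A was -0.559, against 1.07, 0.979 and -0.0116 at equal depth, which follows from the larger number of cells in group A. With the beta or delta chain alone the ratio of B to A was 1.32 and the Shannon difference 0.126, and the cause was not tested. The expanded share of T cell receptors, B minus A, was -5.71 percentage points with separation and -3.19 without it at equal depth.

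Shares from clusters made here, under cell filters, at resolution 2 or without doublets were not run by group, because no label ties the matrix to groups. Tests with edgeR or DESeq2 were not run for the same reason. No paired analysis was possible because each assay has 1 library per group and the numbers in the sample names carry no stated pairing. Between libraries of the matrix, 154 of 190 alternative values for 38 gene list medians stayed within 0.1 log2 units, 129 of 151 for 38 gene ratios stayed within the counting interval, and 7 and 2 changed direction. Depth limits the rarest types and receptors, with 82, 3 and 7 cells for the V-delta 1 chain.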

Other observations

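Tests of explanations in this part were chosen only after the result was seen, except the overlap with the heavy chain alone, which was planned. Values of libraries 1, 2 and 3 of the matrix, which no label ties to a group, are given side by side without a test, and intervals cover counting error only. Classical monocyte-like cells of libraries 2 and 3 had higher levels of MHC class II genes, which present antigen, than those of library 1. The median log2 ratio to library 1 was 1.43 in library 2, with 8 of 8 measured genes higher, and 0.77 in library 3, with 7 of 8 higher. Lrg1, an acute-phase glycoprotein, was at 230 CPM in library 1 (221 to 239), 3.40 in library 2 (1.37 to 7.01) and 2.97 in library 3 (1.09 to 6.46). The neutrophil gene S100a8 moved with it, at 434, 22.4 and 15.8 CPM in these cells and 99.3, 24.99 and 17.2 in B cell-like cells, and cells with markers of 2 lineages were 27.7%, 7.46% and 5.46% of the class. In non-classical monocyte-like cells the MHC class II median was 0.78 in library 2 and 0.97 in library 3, with 8 of 8 genes higher in both. Areg, an epidermal growth factor family ligand, was at 224, 43.0 and 29.6 CPM in them, and Cd93, a C-type lectin-like receptor, at 46.4, 250 and 189. Immunoglobulin constant genes also had a median log2 ratio of 1.31 in classical and 1.35 in non-classical monocyte-like cells of library 2. Among neutrophil-like cells a Retnlg-high cluster (cluster 14) held 2569 of the cells of library 1, 29 of library 2 and 16 of library 3, so that the class was made up differently. In that class all 15 immediate early genes were higher in both other libraries, with medians of 1.08 and 0.91, while the median of all genes was 0.25 and 0.16. Inflammatory cytokines and chemokines had medians of 0.90 and 0.70 there, and Lipg, an endothelial-type lipase, was at 93.2, 4.48 and 2.90 CPM.

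Cyp1a1, which oxidises benzo[a]pyrene, was lower in endothelial-like cells of libraries 2 and 3 than of library 1, at 1218, 730 and 571 CPM, log2 ratios of -0.74 (-0.80 to -0.67) and -1.09 (-1.17 to -1.02). General capillary-like cells (cluster 10) held 71.4% of the class in library 1 and aerocyte-like cells (cluster 19) 46.5% in library 2, so the clusters were also read alone. In general capillary-like cells Cyp1a1 was at 901, 564 and 491 CPM, and in aerocyte-like cells at 2050, 837 and 660. In B cell-like cells, taken as background, it was at 6.11, 2.10 and 3.11. Cyp1b1, a related enzyme, was at 24.0, 42.8 and 2.93 in endothelial-like cells, and the aryl hydrocarbon receptor list as a whole had medians of 0.01 and -0.33, which under other settings ran from -0.24 to 0.00 and from -0.92 to -0.33. NRF2 and glutathione genes had medians of -0.14 and -0.16 there. Heat shock genes, which encode chaperones, were higher by the list median in B cell-, T cell- and regulatory T cell-like cells of libraries 2 and 3. Their median log2 ratio to library 1 was 1.45 and 0.84 in B cell-like, 0.85 and 0.48 in T cell-like and 1.17 and 0.65 in regulatory T cell-like cells. Hspa1b, an inducible member, was at 1176, 9020 and 4543 CPM in B cell-like and 1395, 3896 and 3553 in T cell-like cells. Of B cell-like cells of library 2, 6466 of 13619 lay in cluster 3, led by Cr2 and Fcer2a, against 603 and 567 cells of libraries 1 and 3. Type I interferon response genes had a median of 0.83 in T cell-like cells of library 2, with 13 of 15 higher, and 0.48 in library 3, with 11 of 15 higher. In regulatory T cell-like cells all 15 were higher in library 2, with a median of 0.88, and the median in library 3 was 0.18 and changed sign under other settings (-0.06 to 0.28). Both classes were made up differently between libraries. A CD8 T cell-like cluster (cluster 8) held 1686 of 6098 T cell-like cells in library 1, 1089 of 11786 in library 2 and 1334 of 8904 in library 3. At resolution 2 a cluster led by Foxp3 held only 633, 2396 and 734 cells, and a CD4 T cell-like cluster led by Tnfsf8 held 1169, 2198 and 1147, while the regulatory T cell-like class held 1607, 4499 and 1709, so the class also takes in other T cell-like cells. Heat shock and interferon values were not taken for these clusters apart. Isg15, an antiviral ubiquitin-like protein, was at 21.6, 109 and 38.1 CPM in regulatory T cell-like cells, and Ifit1 at 5.44, 56.4 and 14.8 in NK cell-like cells. Alveolar macrophage-like cells differed from library to library. Their MHC class II median was 0.59 in library 2, with 9 of 9 genes higher, and -0.75 in library 3, with 2 of 9 higher, and the lipid carrier Apoe was at 324, 93.6 and 922 CPM. Cells with markers of 2 lineages were 42.1%, 33.1% and 27.8% of this class. At resolution 2 an alveolar macrophage-like cluster led by Cxcl9 held 230, 6 and 25 cells, so the class was also made up differently. In fibroblast-like cells, of which clusters 16 and 18 held 981 and 659 cells in library 1, 482 and 612 in library 2 and 794 and 749 in library 3, elastin (Eln) was at 278, 224 and 981 CPM.

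Samples of a group shared B cell receptor clones, with a mean overlap of 0.762 within and 0.326 between groups. Light chains that many unrelated B cells share were argued against as the whole cause, because the difference was still 0.340 with the heavy chain alone, though with both chains named pairs within groups B and C had at most 0.00407. In A1, A2 and A3 the most frequent heavy chain was the same, at 6.37%, 6.88% and 5.58% of heavy chain entries. The heavy chain alone therefore cannot tell shared clones from a public heavy chain in group A. Cells given the wrong sample tag were argued against as the whole cause in group A, where T cell receptor chains of 10 or more cells kept a median of 82.3% of their depth-scaled cells in 1 sample, while heavy chains kept 48.9%. Wrong tags as part of the overlap stay open, since pairs within group A also shared 134 to 187 beta or delta chains. Pairs of group A with groups B or C shared 4 to 13. Of 13 such chains of 10 or more cells in group A, 2 lay in 1 sample only. In group B the only one of that size kept 50.8% in 1 sample, so there wrong tags were not argued against. Free immunoglobulin RNA may account for part of the overlap, since receptor-bearing cells in group A came to 191 per 100 annotated B and plasma cells. B cells annotated as another type, and wells that held a B cell and another cell, would add to that number too and were not tested. B cell clones that are truly shared by the sampled lungs stay open for group A and were not tested, as does any effect of cessation. The largest clone with both chains was the same in A1, A2 and A3 and has chains of a public kind. A public receptor carried by unrelated cells therefore stays open there too. For groups B and C the paired chains argue against true sharing as the main cause, as far as the pairing is right. Pairs within group B shared 137 to 160 heavy chains but 0 to 2 clones with both chains. Pairs within group C shared 95 to 101 but 0 to 4. Samples of these groups had 634 to 1890 cells with both chains.

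B1 and B2 held more lymphocytes than any sample of group A. Lymphocytes added to otherwise unchanged tissue were argued against, because fibroblasts per endothelial cell were 17.7 in B1 and 2.07 in B2 against 0.604 to 1.01 in group A. The value of B1 rested on 15 endothelial cells. The ratio was also high in C3, at 4.29, where lymphocytes were 74.6% of cells, and it was 0.531 to 1.20 in B3, C1 and C2. Less alveolar tissue in the piece taken is consistent with B1, which had 0.00752 alveolar type 1 cells per fibroblast against 0.0642 to 0.152 in group A, and 0.0113 type 2 cells against 0.273 to 0.544, from 2 and 3 cells. For B2 it stays open, because type 1 cells were at 0.0105, from 7 cells, and type 2 cells at 0.583, so the 2 types went apart. A loss of fragile cells during dissociation and an effect of cessation stay open and were not tested.

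Receptor-bearing cells per annotated T cell were fewer in groups B and C than in group A. A set of T cells without any receptor message in groups B and C was argued against as the whole cause, because the remaining cells would then keep both chains as often as in group A, 45.9%, while the highest of the 6 samples had 9.06%. A lower recovery of each chain over all T cells of the library stays open. Cells with both chains were 0.669 to 0.838 times the product of the chain rates in these samples, against 0.817 to 0.940 in group A. Independent loss of each chain alone would give a ratio near 1. The test set only an upper limit, so lower ratios could not go against this explanation. Less receptor message per T cell after cessation and a less efficient library would both lower recovery, and with 1 library per group neither was tested. In A1 receptor-bearing cells came to 107 per 100 annotated T cells, so receptors in cells annotated as another type, in wells with 2 cells or from free RNA add to the number in group A by an untested amount.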
